A study of Mus musculus with 2 samples.

How the data were processed

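The series holds 1 library of DNA from chromatin immunoprecipitation (ChIP) of CTCF, a zinc-finger DNA-binding protein that marks insulators and the ends of chromatin loops, and 1 library of whole-cell extract, the sonicated chromatin that was not immunoprecipitated. Per the labels, both came from V6.5 mouse embryonic stem cells, a male line of genotype 129SvJaexC57BL/6, at passages 10 to 15. Per the labels' protocols, fragments were end-repaired, ligated to Illumina adapters, amplified by 15 cycles of PCR, size-selected at about 250 bp with adapters included, and sequenced on the Genome Analyzer. The series title and design text concern direct single-molecule sequencing of small amounts of immunoprecipitated DNA. The libraries described here are the amplified Illumina libraries, and single-molecule reads were not analysed here.

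The authors deposited 1 line per aligned read with its chromosome, start, end, strand and a read number. Per the submitters' processing notes the genome build was mm8. The aligner, its settings and its filters are not given in the sources used here. Every read was 36 bases long. The deposited files contained 0 repeated reads: each combination of position and strand occurred once in each library, also across the 2 extract lanes, so they hold at most 1 read per position and strand. The read numbers in the files skipped 5.7% of values in the ChIP lane, and 1.99% and 3.02% in the extract lanes. The number of PCR copies behind each read is therefore unknown, and counts in the strongest regions have a ceiling set by the number of positions. Starts were read as counted from 0 and are given here counted from 1; the files do not state this, so positions may be off by 1 bp.

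The ChIP library held 2371134 reads and the extract library 4691104 reads. On the assembled chromosomes 1 to 19, X and Y these were 2370818 and 4686960 reads, or 0.901 and 1.78 reads per kb. With 1 library per group there is no replicate check on any difference between ChIP and extract. Tests on reads compare these libraries and not conditions, and intervals (95%, exact Poisson or Clopper-Pearson) and floors of 3 counts cover counting error only.

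Fragment length was taken from the strand cross-correlation, the Pearson correlation of plus- and minus-strand 5′ ends as one strand is shifted against the other in steps of 5 bp up to 500 bp. The curve was averaged over 5 points and its maximum sought from 60 bp on. Reads were moved 102 bp towards their 3′ end, which is 50% of the fragment length. Enriched regions were called in 200-bp windows every 50 bp with an exact Poisson test. The expected count was the largest of the genome average (0.18 reads per window) and the extract reads in the surrounding 1 kb, 5 kb and 10 kb, scaled by the ratio of library totals (0.506). Windows passed at a Benjamini-Hochberg adjusted p under 0.001, over the 6352508 windows with a ChIP read, and at least 5 times the expected count. The largest passing p was 2.83e-05. Passing windows within 200 bp were joined. The same procedure with the libraries exchanged gave the background count. To measure ChIP reads in regions without circularity, regions were called on a random 50% of the ChIP reads (subset A) and the other reads (subset B) were counted in them. The extract was not split, so its reads both set the expected counts and were counted.

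Chromosomes were compared by regions per Mb and per 1000 extract reads. Clustering was tested with 10000 random placements of the regions of each chromosome among its extract reads. For dosage, reads outside regions and their 1-kb flanks were counted in 1-Mb bins with at least 50 reads in each library. A quadratic trend of log2 extract reads on log2 ChIP reads was fitted on 17 reference autosomes, and the departure from it was taken per bin. An autosome was left out of the reference where its median departure was over 0.3 or where it held a stretch of at least 20 bins differing from its other bins by that much. The dosage bins, and the rule that a stretch leaves at least 5 bins outside it, were set after the data had been seen.

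The caller was tested on simulated data of 4 chromosomes with 215669 background reads drawn from the extract. It recovered 56% of 50 sites holding 5 reads and 100% of 50 sites each holding 10, 20 or 40 reads, with 3 false regions. From the simulated site reads alone, a fragment length of 200 bp was returned as 190 bp, and of 20 randomly placed region sets 0 gave a clustering p under 0.05. A simulated gain of 1.5-fold was returned as 1.51-fold with its bounds at the simulated bins.

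Before the data were examined, the named regions were set as the 20 with the most ChIP reads among regions called under 5 other settings of window, shift and scaling (keeping repeated reads, also named in that rule, alters nothing here), 1 region at the median read count, the weakest region, and the 100-kb stretch with the most regions. Chromosomes were to be named where regions per extract read lay over 1.2 times or under 0.8 times the autosome median, and for dosage where reads outside regions did so in both libraries. Alternatives covered the window, shift, scaling, thresholds, expected value, extract depth and strand requirement. Annotation of regions, the CTCF motif and lists of genes had been planned as well. They were not run because no mm8 genome or annotation was used here; the gene table at hand was for GRCm38 and positions were not converted. Regions are given by mm8 position without gene names. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.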

Results

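CTCF-bound DNA was profiled in V6.5 mouse embryonic stem cells by sequencing 1 ChIP library and 1 whole-cell extract library as its control. The ChIP library came from 1 sequencing lane with 2371134 reads, and the extract from 2 lanes with 2528408 and 2162696 reads. Plus-strand reads made up 50.01% of the ChIP reads (95% interval 49.95 to 50.08) and 50.03% of the extract reads (49.98 to 50.07). There were no replicates, so every difference below is between these 2 libraries and its errors are counting errors.

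The first question was whether the immunoprecipitated reads gathered at discrete sites. In the ChIP library, plus- and minus-strand reads were most correlated at a shift of 205 bp, with a correlation of 0.0106 against a minimum of 0.0023. The extract showed no comparable maximum. Its correlation at its own best shift of 175 bp was 0.000565, below the value of 0.00078 at the read length. Over the 19 autosomes taken singly, the ChIP maximum lay between 165 and 220 bp (SD 13.5 over chromosomes).

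CTCF-enriched regions numbered 34781, against 30 (95% interval 20.2 to 42.8) when the extract was tested over the ChIP in the same way. The regions covered 14.8 Mb, or 0.563% of the assembled chromosomes, with a median length of 450 bp. The median region held 15 ChIP reads and 1 extract read. Regions in the 5th to 95th percentile held 5 to 42 ChIP reads. Reads of both strands were present in 34350 regions (98.76%). No extract read fell in 10579 regions (30.4%). Of the 24202 regions with an extract read, 193 (0.797%) had a ChIP-to-extract ratio whose 95% interval reached 1. For these, the excess over the whole region was not detectable at this depth with the libraries scaled by their totals. Background bins are the 10-kb bins holding a read with at most the median ChIP count. Scaling the extract by them (0.246 in place of 0.506) would raise these ratios, and the count of 193 was not repeated that way. These bins were chosen for their low ChIP counts, so the value of 0.246 may be biased downwards. Results with this scaling may then overstate the excess of ChIP reads. Regions with fewer than 10 ChIP reads made up 27.6% of the total and those with at least 20 made up 37.6%.

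Reads not used for calling showed the same concentration. Subset A of the ChIP reads gave 26876 regions, and 22.2% of the held-out reads fell in them (263447 of 1184442 reads, 95% interval 22.2 to 22.3). The same regions held 0.767% of the extract reads (0.759 to 0.775), a 29-fold lower share. Those extract reads had also set the expected counts, so their share may be biased downwards. Subset B called 27139 regions. Of the subset A regions, 80.4% overlapped a subset B region by at least 1 bp, and the summits of overlapping regions lay a median of 51 bp apart. These subsets are draws from 1 library and measure sampling only.

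Around the summits the strands were ordered as around a point of binding. In held-out reads, the median plus-strand 5′ end lay 104 bp upstream of the summit and the median minus-strand end 95 bp downstream, an offset of 199 bp. In the same held-out reads, density within 300 bp of the summit was 8.24 times that at 400 to 500 bp. In the extract this ratio was 1.12 around the summits of all regions.

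**Figure D1:**
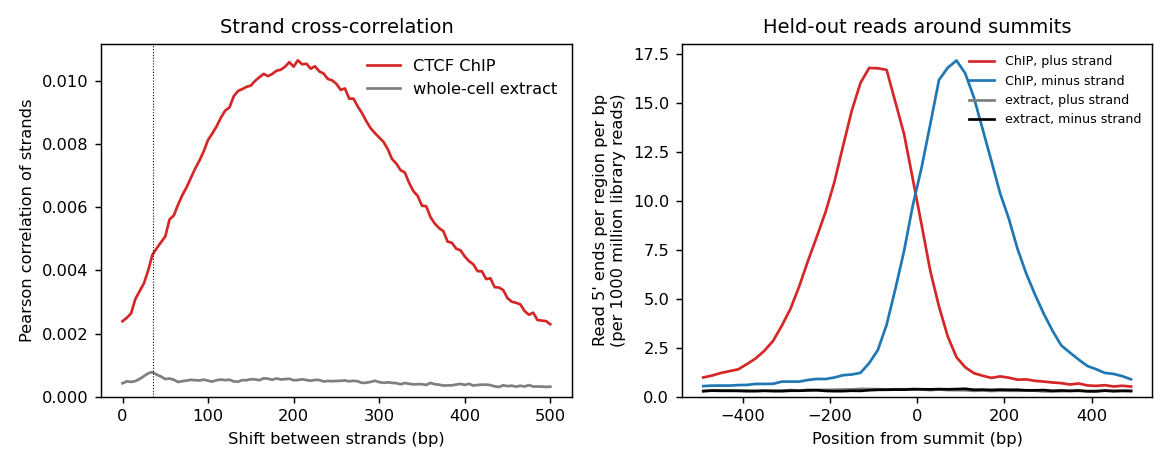
Left, Pearson correlation of plus- and minus-strand 5′ ends against the shift in bp for the ChIP and the extract, with the 36-base read length dotted. Right, held-out ChIP reads and extract reads by strand around subset A summits, in 5′ ends per region per bp scaled by library size. The ChIP correlation peaks at 205 bp and the ChIP strands lie 199 bp apart around the summits, while the extract is nearly flat.

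The strongest regions lay on 12 chromosomes. The 20 regions with the most reads held 110 to 155 ChIP reads, or 46.4 to 65.4 RPM (ChIP reads scaled by library size), and were 550 to 1400 bp long. This ranking was not corrected for chromosome dosage. Of the 20, 4 lay on chromosome 8 and 3 on chromosome 4. ChIP reads outside regions were there at 1.181 and 1.013 times the autosome median per Mb. The strongest, on chromosome 8 from 73558551 to 73559650, held 155 ChIP reads (65.4 RPM, 95% interval 55.5 to 76.5) and 11 extract reads, a 27.9-fold excess (15.1 to 57). Folds given for regions scale the libraries by their totals. With the extract scaled by background bins, the largest window of this region rose from 111 to 228 times the expected count. The next, on chromosome 2 from 32734301 to 32734950, held 144 ChIP and 5 extract reads (56.9-fold, 23.8 to 178). A region on chromosome 8 from 28586401 to 28587250 held 135 and 4 reads (66.7-fold, 25.5 to 248). Regions on chromosome 15 from 77163601 to 77164400 and on chromosome 5 from 120363251 to 120363900 each held 132 ChIP reads, with 6 and 4 extract reads. On chromosome 4, the regions from 137554701 to 137555450, from 136996651 to 136997300 and from 134981051 to 134981800 held 128, 117 and 111 ChIP reads.

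Some strong regions held few or no extract reads. The region on chromosome 8 from 24703101 to 24703750 held 119 ChIP reads and 0 extract reads. With a floor of 3 extract reads put in, the ratio was 78.4-fold, a point value without a counting interval. The region on chromosome 18 from 36065351 to 36066150 held 117 ChIP and 2 extract reads (116-fold, 95% interval 31.3 to 966). The region on chromosome 9 from 111134551 to 111135200 held 113 and 2 reads (112-fold, 30.2 to 934). These intervals overlap that of the strongest region.

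One region among the 20 differed from the others. It lay on chromosome 1 from 196942101 to 196942650 and held 112 ChIP reads and 34 extract reads, a 6.51-fold excess (95% interval 4.4 to 9.86). Its reads were split into 26 on the plus strand and 86 on the minus strand (exact binomial test, two-sided, adjusted p = 2.2e-07 over the 20 regions). It was the 1 region of the 20 with an adjusted p under 0.05 for strand balance.

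A region at the median count, on chromosome 1 from 7533351 to 7533800, held 15 ChIP reads and 1 extract read (29.7-fold, 95% interval 4.56 to 1250). The weakest region by its largest window lay on chromosome 9 from 3030101 to 3030300. It held 25 ChIP and 32 extract reads (1.54-fold by library totals, 0.877 to 2.69) and was called in 12 of the 17 alternative settings. Its largest window was 5.15 times the expected count, and 10.6 times with the extract scaled by background bins.

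Regions were unevenly spread over the chromosomes. Chromosome 11 was the densest autosome with 2639 regions, or 21.67 per Mb (95% interval 20.85 to 22.51), which is 1.524 times the autosome median. Chromosome 19 followed with 17.16 per Mb (16.13 to 18.22) and chromosome 5 with 16.89 per Mb (16.24 to 17.55). Chromosome 3 with 10.08 per Mb (9.597 to 10.59) and chromosome 14 with 10.16 per Mb (9.611 to 10.74) were the sparsest autosomes, and chromosomes 1, 12 and 13 each had 10.73 per Mb. Chromosomes 3, 5, 12, 13, 14 and 19 are named after their values were seen. The intervals of chromosomes 11 and 3 do not overlap.

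Relative to extract reads, the order changed for some chromosomes. Chromosome 11 had 10.16 regions per 1000 extract reads (9.772 to 10.55) and chromosome 7 had 9.745 (9.36 to 10.14), 1.309 and 1.256 times the autosome median. Chromosome 1 had 4.263 (4.083 to 4.448), which is 0.5496 times the median, while its ratio per Mb was 0.7551. Outside regions, the extract held 1.43 times the autosome median of reads per Mb on chromosome 1. With the extract thinned there and over the raised part of chromosome 4, chromosome 1 had 6.822 regions per 1000 extract reads (6.542 to 7.11), or 0.8653 times the median, and chromosome 3 was then lowest with 6.283 (5.979 to 6.597).

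Chromosome X, of which male cells have a single copy, held 673 regions, or 4.066 per Mb (3.765 to 4.385). Its density per Mb was 0.294 times that of the autosomes (0.272 to 0.317), and its density per extract read was 0.956 times (0.885 to 1.03), an interval that includes 1. Outside regions, X held 0.3316 times the autosome median of extract reads per Mb, which raises its density per extract read. The value of 0.956 is therefore no measure of equal density of CTCF sites. This value was 0.736 (0.665 to 0.812) at an adjusted p under 1e-06, 0.916 (0.848 to 0.988) with the extract scaled by background bins and 0.904 (0.837 to 0.976) with the raised stretches thinned, intervals that lie below 1. The median X region held 8 ChIP reads and the median autosomal region 16. The strongest X region, from 71926401 to 71927350, chosen after its values were seen, held 103 ChIP reads and 0 extract reads. With a floor of 3 extract reads put in, the ratio was 67.9-fold, a point value without a counting interval. Chromosome Y gave 18 regions, of which 17 held no extract read. The whole chromosome held 15 extract reads, so the expected count there came mostly from the genome average.

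**Figure D2:**
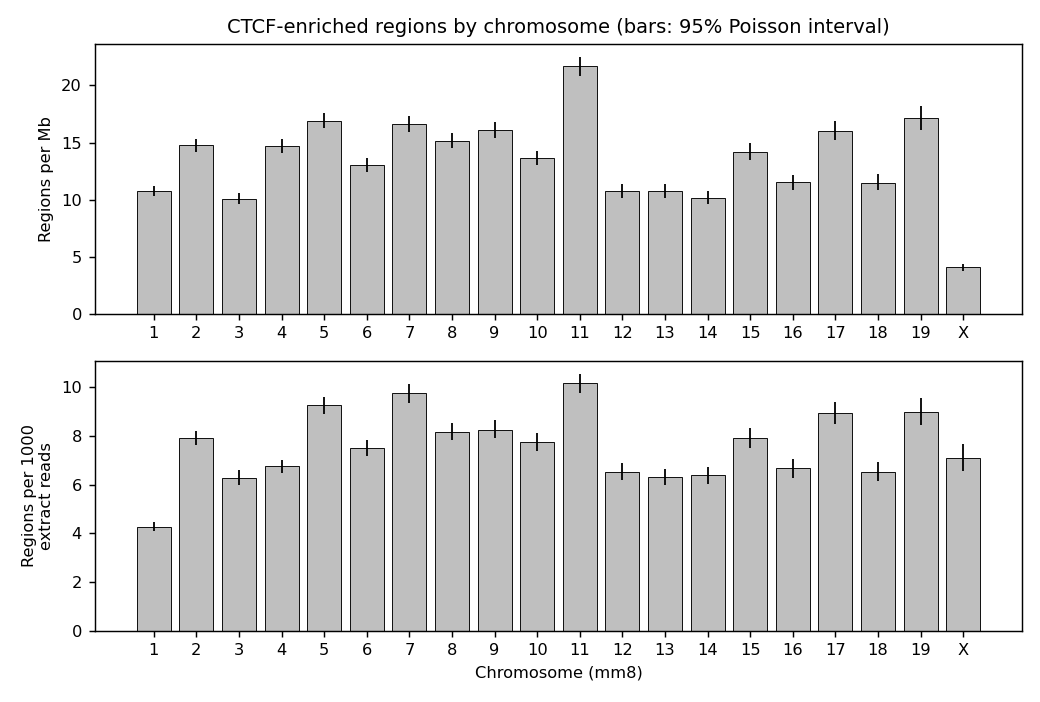
CTCF-enriched regions per Mb (top) and per 1000 extract reads (bottom) for chromosomes 1 to 19 and X in mm8, with bars from 0 and 95% Poisson intervals as lines. Chromosome 11 is highest in both panels, X falls to 4.066 per Mb but reaches 7.1 per 1000 extract reads, and chromosome 1 lies at 4.263 per 1000 extract reads, which becomes 6.822 with the raised extract thinned.

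Regions lay close together more often than random placement gave. Of the 34760 pairs of neighbouring regions, 28.7% had summits within 10 kb, against 16% when the regions of each chromosome were placed at random among its extract reads, a ratio of 1.79. The one-sided permutation p was 0.0001, the smallest that 10000 draws can give. Within 5 kb the shares were 16.7% and 8.83%, and within 50 kb 68.6% and 54.7%. Regions are not independent replicates. The 100-kb stretch with the most regions lay on chromosome 18, where 20 summits fell between 37794889 and 37891891. Those regions held 447 ChIP reads and 43 extract reads. The genome average was 1.32 regions per 100 kb. A permutation test of this stretch was chosen after it was seen and decides nothing over the genome. In 1000 random placements among extract reads, the densest 100 kb held a median of 44 regions and lay in each draw on chromosome 11, in the 1-Mb bin that starts at 3 Mb and whose first 100 kb held 4361 extract reads. On chromosome 18 alone, which was picked for this stretch, the random maximum had a median of 7 and a highest value of 12.

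The number of regions depended on the number of ChIP reads. With 20% of the reads, 14735 regions were called, with 40% 23719, with 60% 28964 and with 80% 33127, which is 95.2% of the full count. A second draw gave 15770, 23837, 29023 and 33033. Regions missed at 80% of the reads had a median of 6 ChIP reads in the full data, and those found had a median of 17.

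**Figure D3:**
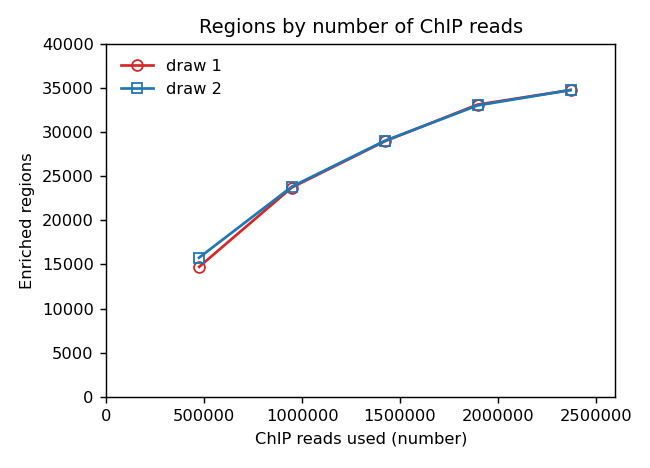
Number of CTCF-enriched regions against the number of ChIP reads used, for 2 random draws of 20, 40, 60 and 80% of the reads and for all reads. The count rises from 14735 and 15770 to 34781 and had not levelled off.

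The extract was also read for chromosome dosage, since it sets the background of every region. Outside the regions, X was low in both libraries, at 0.3316 times the autosome median of reads per Mb in the extract and 0.3508 times in the ChIP. Y was at 0.002389 times in the extract and 0.2685 times in the ChIP, and at 0.00449 times in the extract with covered 10-kb bins as the exposure. Chromosome 1 was at 1.43 times in the extract and 0.9536 times in the ChIP, and chromosome 4 at 1.222 and 1.013 times. Chromosomes 1 and 4 passed the naming limit in the extract alone and are named after their values were seen. Chromosome 11 was at 1.172 times in the extract and 1.252 times in the ChIP.

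**Figure D4:**
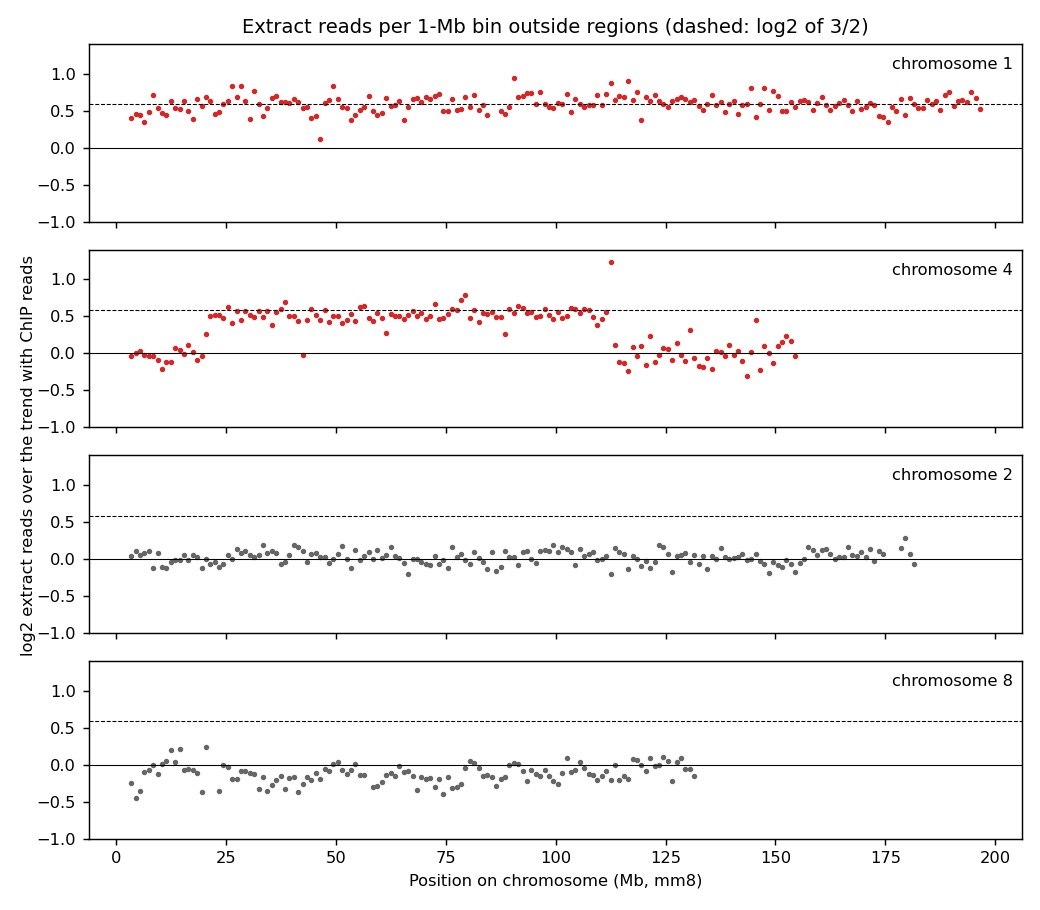
Extract reads per 1-Mb bin outside regions, as the log2 departure from their trend on ChIP reads in the same bins, along chromosomes 1, 4, 2 and 8 (mm8, position in Mb); the dashed line is log2 of 3/2, or 0.585. Chromosome 1 has a median of 0.59 along its length, chromosome 4 a mean of 0.52 from 20 to 113 Mb and -0.01 elsewhere, chromosome 2 a median of 0.03 and chromosome 8 a median of -0.13.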

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

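Extract lanes used singly, extract thinning over raised stretches, leaving out chromosome Y, placement among ChIP reads and held-out summits were chosen after seeing the data. The count of regions ranged from 26813 (adjusted p under 1e-06) to 51300 (under 0.05) and stayed within 1.5 times 34781 in all 17 settings. With the libraries exchanged, these 2 thresholds gave 10 and 650 regions. Without the extract, 44037 regions were called and the exchanged count was 489. Scaling the extract by background bins, which may be biased because the bins were chosen for low ChIP counts, raised the largest window from 111 to 228 times the expected count in the strongest region. In the weakest region it rose from 5.15 to 10.6 times. The share of held-out reads in regions was 22.3% with the subsets exchanged, 17.3% at 1e-06 and 23.3% with the extract scaled by background bins, against 22.2%. The X-to-autosome ratio of regions per extract read fell from 0.956 to 0.736 at 1e-06, 0.916 with background bins and 0.904 with the raised stretches thinned; the cause was not tested. The clustering ratio stayed between 1.24 and 1.97 (permutation p = 0.0001, the smallest that 10000 draws can give), and was 1.69 within 10 kb when regions were placed among ChIP reads outside regions. The fragment length from chromosome 1 alone was 165 bp, against 205 bp. The strand offset was 205 bp in the strongest 1000 regions and 199 bp in held-out reads, against 202 bp. Extract reads on chromosome 1 were 1.408 times the median with covered 10-kb bins as the exposure, against 1.43. Keeping repeated reads gives no separate value, since each position and strand occurs once. Annotation, motif and gene lists were not run. No paired analysis was possible because each group has 1 library; for the same reason no replicate could be left out. Depth limits the weak regions most: those missed at 80% of the reads had a median of 6 ChIP reads in the full data, against 17 for those found. In the simulated data, 56% of sites with 5 reads were recovered. The adjusted threshold there rests on far fewer enriched windows, so this is no recovery rate for these data.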

Other observations

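All tests in this part were chosen after the result was seen, except the test of regions lost on chromosome 1 and the subset B test of regions below the threshold. The random windows beside the latter were added afterwards. The thinning used for the former was chosen after the raised extract had been seen, with its bounds set before its own result.

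The extract reads were raised over chromosomes 1 and 4. After the trend with ChIP reads was removed, the median log2 departure was 0.59 on chromosome 1 (SD 0.114 over 192 bins), a 1.51-fold excess. On chromosome 4 it averaged 0.52 (SD 0.126, 93 bins, 1.44-fold) from 20 to 113 Mb and -0.01 (SD 0.139, 59 bins) on the rest of that chromosome. The medians of the reference autosomes other than chromosome 8 lay between -0.01 and 0.04.

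The median of 0.59 on chromosome 1 remained after removal of the trend with ChIP reads. Chromosome 1 had been left out of that fit because of its departure, so this outcome was fixed and tests nothing. Base composition was not measured, and a trend with it or with openness stays open. The excess was spread along chromosome 1 and not held by a few crowded loci, with 99.5% of its bins above 0.3. A median of 0.59 already requires most bins to lie above 0.3, so this describes the excess and is no separate test. A fault of 1 lane does not account for the raised reads, since the lower lane median was 0.59. Extra copies in the cells of the extract stay open too. In all cells, 3 copies against 2 would give 0.585, and the mean on chromosome 4 was 0.52 (standard error 0.0131 over bins). Those bins are neighbours in 1 library, and the bounds of the stretch were chosen on the same values. The error is therefore too small to set 3 copies aside, and chromosome 8 as a whole departed by -0.13. A gain in part of the cells could give any lower value. Whether the extract and the ChIP came from different cultures was not tested. Thinning the extract to the level of the other chromosomes raised the regions on chromosome 1 by 6%, from 2115 to 2242, between the bounds set beforehand for a loss and for none, and left their density at 0.801 times the autosome median per Mb, so the raised extract may account for part of the low density of chromosome 1.

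Chromosome Y was nearly absent from the extract. It held 732 ChIP reads, spread over 24 of 28 stretches of 100 kb, and 15 extract reads, a rate of 1.04% of that in the ChIP (95% interval 0.577 to 1.72). Lower depth does not account for this, since the extract held 1.98 times as many reads as the ChIP. Stricter removal of repeated sequence from the extract was not tested, because no mm8 genome was used here. An extract from cells with a pair of X chromosomes would put X at 0.87 on the log2 scale by the trend, and its median was -0.2. Loss of Y from the cells of the extract stays open. It would leave X at the -0.13 of a single copy in both libraries. The median seen, -0.2, lay below that, with a standard error of 0.02 for the mean over X bins. The margin set for this explanation, after the result was seen, was not met. Neighbouring bins of 1 library are not independent, so that error may be too small. Anything that spares X would leave the same -0.13, so X cannot decide this. A difference in origin between the samples is open too.

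Regions below the threshold may hold further sites. At an adjusted p under 0.05, subset A gave 6676 regions that overlapped none of the 34781, with a median of 3 reads. ChIP reads of subset B fell in them at 2.86 times the rate of the extract (95% interval 2.74 to 2.99). The same extract reads had set the expected counts of these regions, so the ratio may be biased upwards. Subset B reads had helped to call the 34781 regions, so leaving out overlaps with those may bias it downwards. The subset B reads were thus not fully held out here. In 6676 windows placed around subset A reads outside regions and their 1-kb flanks this ratio was 0.948 (0.88 to 1.02). The 6676 regions could lie within those flanks, so the windows are not matched to them. How far reads beside called regions add to the ratio of 2.86 was not tested. Sites too weak to be called at this depth are a candidate explanation; regional differences in base composition were not tested, because no mm8 genome was used here.

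Chromosome 8 had a median log2 departure of -0.13 (SD 0.13 over 126 bins), with -0.13 in each extract lane and with reads outside regions at 1.181 times the autosome median in the ChIP and 1.035 times in the extract, against an SD of 0.01 between the medians of the other reference autosomes. Mitochondrial reads made up 0.0133% of the ChIP library (95% interval 0.0119 to 0.0149) and 0.0883% of the extract (0.0857 to 0.0911). ChIP reads outside regions were higher where regions were dense: in 1-Mb bins with 0 to 5 regions the median log2 ratio of ChIP to extract was -0.59 (SD 0.14, 601 bins), and in the 247 bins with at least 31 regions it was -0.29 (SD 0.127). Of the 30 regions called with the libraries exchanged, 10 lay on chromosome 1 and 5 on chromosome 9. Those on chromosome 1 included a group between 90051751 and 90094750, and all of those on chromosome 9 lay between 2999851 and 3023000.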
